A study of Arabidopsis thaliana with 3 samples.

How the data were processed

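Whole-genome bisulfite sequencing was analysed for 3 libraries of 20-day-old Arabidopsis seedlings, 1 each from wild type, a swi3b mutant and a sil1 mutant, grouped by the genotype that the labels give. Per the labels' protocols, DNA was extracted with a column kit, ligated to premethylated adapters and converted with a bisulfite kit. Per the submitters' processing notes, reads were trimmed with Trimmomatic and aligned and called with BS-Seeker2 on TAIR10. The versions, the treatment of duplicate reads and the filters on reads are not given in the sources used here. The deposited tables of the authors hold 1 line per covered cytosine with its strand, position, context, the methylation level as a fraction, and the counts of methylated reads and of all reads. The deposited fractions matched the ratio of the deposited counts in every line within the rounding of the files, and the counts are whole numbers that were not normalised. Lines without a context, 92, 101 and 91 in wild type, swi3b and sil1, were left out. Since duplicates may remain and reads of a molecule overlap several cytosines, read counts are not independent molecules.

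Levels were read-weighted, the methylated reads over all reads of cytosines with at least 4 reads, on chromosomes 1 to 5. The chloroplast chromosome gave the unconverted background, between 0.105% and 0.135% over contexts and libraries. The means of the coverage per listed nuclear cytosine were 13.5, 13.9 and 14.4 reads in wild type, swi3b and sil1, and the medians 7, 6 and 8. Coverage was uneven, with 61.7%, 67.6% and 55.6% of calls on cytosines above 3 times the median. Read-weighted levels therefore depend on where the reads lie, and alternatives with equal weights or the same cytosines in all libraries were computed. Intervals are 95% Wilson intervals of the reads, and for medians over segments 95% intervals of the order statistics.

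For the comparisons, reads of 1 context were summed in 100 bp windows with at least 4 cytosines covered by at least 4 reads in all 3 libraries, which left 293138 windows in CG, 303917 in CHG and 959404 in CHH. Each mutant was compared with wild type, and swi3b with sil1, by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over all windows of the context. A window was called lower or higher at an adjusted p under 0.01 and a difference of at least 40 percentage points in CG, 20 in CHG or 10 in CHH. Segments, gene bodies and flanks were tested in the same way with at least 10 cytosines. The test compares reads of 2 libraries and cannot show a difference between genotypes beyond them. The ratio of the variance between the strands of a library to the binomial variance averaged 1.92 in CG, 2.21 in CHG and 4.02 in CHH. The reads thus vary more than the test assumes, though sites of the strands can differ in truth. The ratios are upper bounds only for the variance within a library. They hold no variance between plants or libraries, which 1 library per genotype cannot show. Tested on simulated data made from the wild-type levels for the comparison of swi3b with wild type, the procedure recovered 90.5% of 200 windows lowered by 50 points in CG, 51.5% of 200 lowered by 30 points in CHG and 50.5% of 200 lowered by 15 points in CHH, with 1, 0 and 1 false calls over the 293138, 303917 and 959404 windows. Other draws were tested at 0.5, 1 and 2 times the coverage. The simulated reads carried binomial variance only, without the extra variance seen between strands. The few false calls therefore give no rate of false calls for the libraries themselves.

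A genome sequence and an annotation of transposable elements were not used here. The gene table used is of assembly TAIR10.1 and gives names, gene classes and neighbours, without strand, exons or element families. By the rule fixed for that case, 100 bp windows with a wild-type CHG level of at least 20%, merged when at most 1 window apart, stood in for transposable elements. They formed 30371 segments covering 10.2 Mb, 6623 of them at least 500 bp long. Pseudogenes, the class that holds the transposable element genes, were tested as bodies. The planned 1 kb upstream of genes became 1 kb on both sides, called flanks. Gene positions of the table were used to sum reads after a check of the register. Of 625 tRNA genes, 80.3% had a CG at the conserved position at a shift of 0 bp, 6.56% at 1 bp and at most 0.32% at the other shifts up to 3 bp. Printed positions are those of the deposited tables. Pericentromeres were the sequence within 2 Mb of each centromere.

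Gene lists were fixed before the data were examined. They held the DNA methylation machinery, SWI/SNF members, histone deacetylases, genes with methylation-dependent silencing or epialleles, transposable element genes, the rRNA genes, and pseudogenes as 1 list. All members matched the gene table by locus identifier, and the 4 rRNA genes were those the table classes as rRNA. The median of a list was set against 10000 random lists of the same size drawn from 20 bins of the mean level over the libraries. The rule for named loci was also fixed then. It took, per mutant and context, the 5 segments of at least 500 bp with the largest loss and the 2 with the largest gain past the threshold, the 5 protein-coding genes with the largest CHG loss in the flanks and the 3 with the largest CG loss in the body, every list member past the threshold, and HDA6, SWI3B, FWA, SDC, ROS1 and IBM1. The 45S rRNA genes, beyond their list, were followed further because of their values.

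The overlap of windows lower in both mutants was set beside the product expected of independent lists and beside libraries simulated without change at the coverage of each mutant, since both comparisons share 1 wild-type library. It was also counted with swi3b compared with wild type on the forward strand and sil1 on the reverse strand, in windows with at least 2 cytosines on each strand. Independent lists were then formed within 5 classes of wild-type level by 5 of coverage, among windows with enough methylation to fall, with intervals from 1000 resamples of 100 kb blocks. Alternatives fixed beforehand were a minimum of 10 reads, 200 bp windows, differences of 60, 40 and 20 points, thinning to equal depth, leaving out cytosines above 3 times the median coverage, equal weights for cytosines, subtraction of the chloroplast level, single strands, and a random split of the wild-type reads. Alternatives chosen after seeing the data were scaling reads by the variance between strands, segments chosen by the mean of the libraries, leaving out the 45S rRNA regions, the coverage limit for levels, the use of the same cytosines in all libraries, single strands for the overlap, and all those for the segment medians. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and pyarrow 21.0.0.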

Results

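DNA methylation was measured by whole-genome bisulfite sequencing in Arabidopsis thaliana seedlings grown for 20 days under long days. In this assay, bisulfite converts unmethylated cytosines so that they read as thymine, and the share of reads that still show cytosine is the methylation level. There were 3 libraries, 1 each from wild-type plants of the Col accession, from a swi3b mutant and from a sil1 mutant. SWI3B is a core subunit of SWI/SNF chromatin remodelling complexes, and SIL1 is listed in the gene table as a synonym of HDA6, a histone deacetylase of heterochromatin. The study asked how the proteins act in transposon silencing, so both mutants were compared with wild type in the CG, CHG and CHH contexts (H is A, C or T), and then with each other. The nuclear chromosomes had 489654067 cytosine calls in wild type, 514242153 in swi3b and 547878753 in sil1, at median coverages of 7, 6 and 8 reads per listed cytosine. In all libraries, 20379080 nuclear cytosines had at least 4 reads. With 1 library per genotype there was no replicate check, so Fisher's exact test on the reads compared these libraries and not the genotypes, and 95% Wilson intervals cover counting error only. The chloroplast, taken as unmethylated, gave a background of 0.124%, 0.118% and 0.105% in the CHH context in wild type, swi3b and sil1.

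The bodies of the mutated genes carried little methylation. The SWI3B body (AT2G33610) had CG levels of 3.75% in wild type, 3.49% in swi3b and 3.87% in sil1, and its CHG levels were at or below 0.471% in the 3 libraries. The 1 kb flanks of SWI3B had CG levels of 31.2% in wild type, 33.5% in swi3b and 32.2% in sil1, and CHG levels of 4.55% in wild type and 8.38% in swi3b, a difference under the threshold. The HDA6 body (AT5G63110) had CG levels of 1.43%, 0.301% and 0% in wild type, swi3b and sil1, over 280, 332 and 352 reads. Methylation levels do not report the mutations, so the genotypes were taken from the labels.

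The sil1 library had less non-CG methylation than wild type along whole chromosomes, and the swi3b library had slightly more CHG methylation. The nuclear CHG level was 15.4% in wild type, 11.1% in sil1 and 16.1% in swi3b, so that sil1 differed from wild type by -4.34 percentage points (95% interval -4.35 to -4.33) and swi3b by 0.6998 points (0.687 to 0.713). Within the pericentromeres, the repeat-rich sequence around the centromeres, the CHG level was 40.6% in wild type, 32.3% in sil1 and 42.4% in swi3b. CHH levels were 3.33% in wild type, 3.28% in swi3b and 2.72% in sil1. CG levels were 37.1%, 36.7% and 33.8%. The CG difference of sil1, -3.29 points, became -0.398 points when the same cytosines were used in all libraries and each cytosine had equal weight, whereas the CHG difference was then -2.85 points. The CG difference of swi3b, -0.415 points, lay between -1.64 and 0.0951 points over the alternatives, and its CHG difference became -0.426 points when highly covered cytosines were left out library by library but was 0.639 points when that limit was applied to the same cytosines in all libraries.

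**Figure D1:**
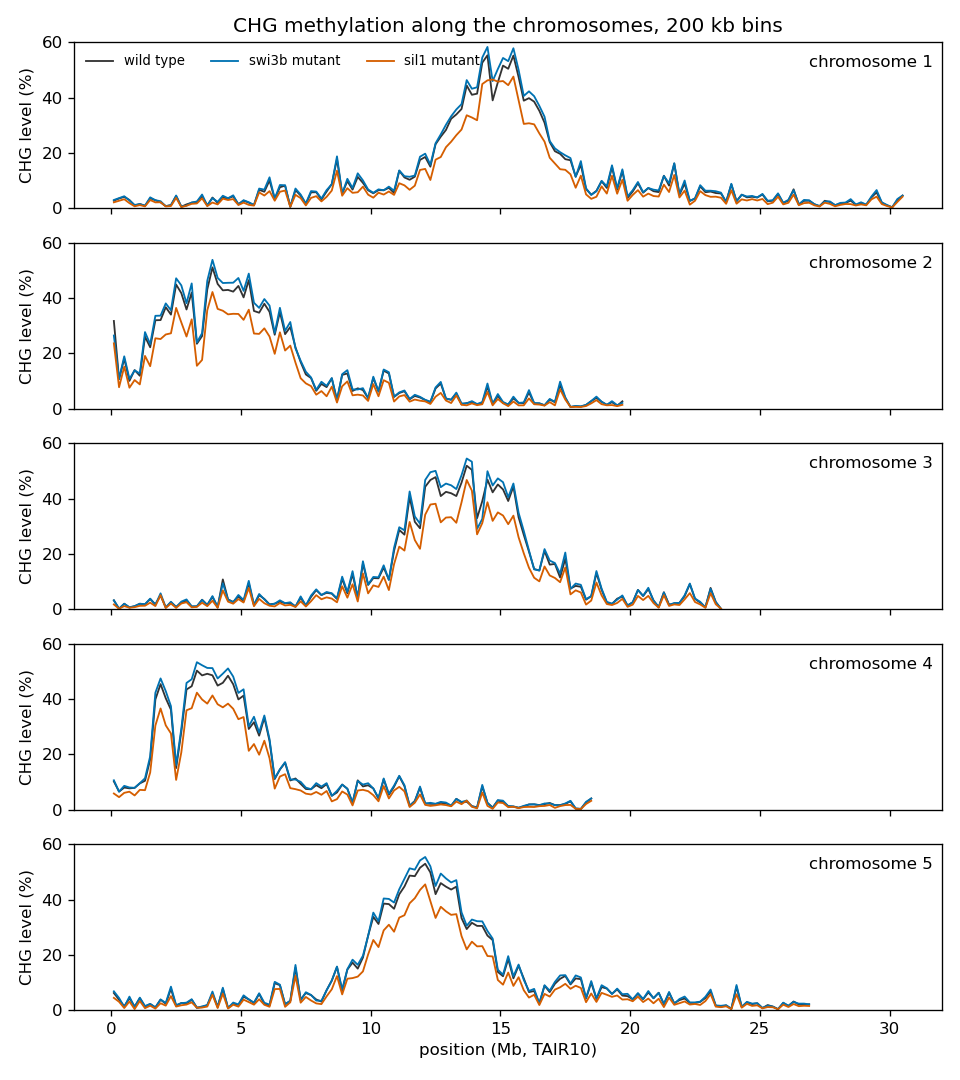
CHG methylation level (%, y axis) in 200 kb bins against position (Mb, x axis) on the 5 chromosomes, 1 line per library. The sil1 line lies below wild type in 591 of 598 bins and the swi3b line lies above it in 500 of 598, with the widest gaps in the pericentromeric peaks.

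CHG levels were lower in sil1 than in wild type over most CHG-methylated segments of the genome. These 30371 segments were merged from 100 bp windows with wild-type CHG levels of at least 20%, and they stand in for annotated transposable elements here. Of 16473 segments with enough CHG sites, 2063 were lower in sil1 and 2 were higher by Fisher's exact test, and the median difference was -9.68 points (95% interval -9.81 to -9.53). A negative difference was seen in 91.2% of the segments. CG methylation of the same kind of segment passed the threshold of loss in 99 of 13878 segments, with a median difference of 0.728 points. The read-weighted CG level over all segments had the opposite sign, with 85.6% in wild type and 84.5% in sil1, or -1.09 points. CHH methylation passed in 455 of 28702 segments, with a median of -1.29 points. Pseudogene bodies, the class of the gene table that holds the transposable element genes, were lower in CHG in 273 of 4297 cases and higher in 0, with a median difference of -8.47 points. Among protein-coding genes, 247 of 25246 bodies and 153 of 27252 flanks were lower in CHG, and 29 of 25302 bodies were lower in CG. With the stricter differences of 60, 40 and 20 points in CG, CHG and CHH, the lower segments numbered 51, 133 and 35, and leaving out highly covered cytosines left 34 in CG and 1354 in CHG.

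**Figure D2:**
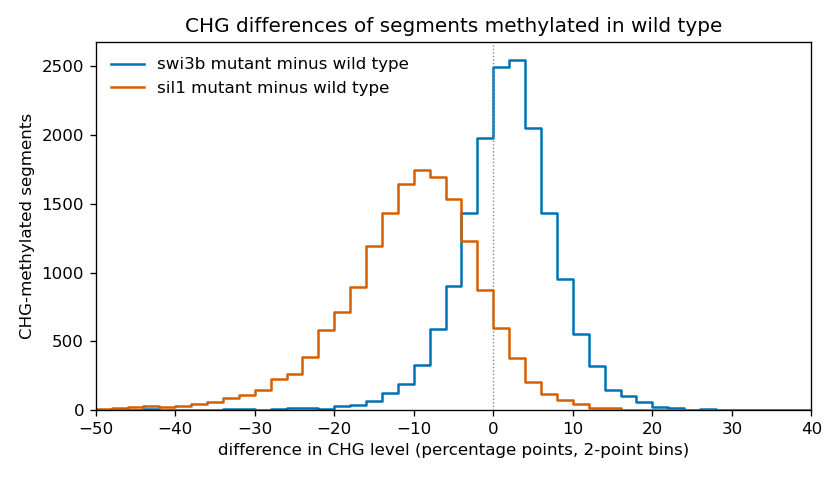
Number of CHG-methylated segments (y axis) by difference in CHG level from wild type (percentage points, x axis, 2-point bins), 1 line per mutant library. The sil1 distribution has its median at -9.68 points and the swi3b distribution at 1.99 points.

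At several loci sil1 lost nearly all methylation. At chromosome 2, 9047901 to 9048500 (TAIR10), over AT2G21100 and AT2G21105, the CG level was 89.0% in wild type, 86.8% in swi3b and 0% in sil1 (0 of 393 reads, upper limit 0.968%), the CHG level was 62.9%, 59.7% and 0.232%, and the CHH level was 17.4%, 12.8% and 0%. Between BAM5 (AT4G15210), a beta-amylase gene, and the transporter gene ABCG41 (AT4G15215), the segment at chromosome 4, 8670301 to 8671200, had CG levels of 91.3%, 83.6% and 0.703%, and CHG levels of 55.8%, 53.3% and 0.318%. Its loss was also seen in the ABCG41 flanks, where CHG fell from 40.7% to 0% in sil1 (0 of 1518 reads, upper limit 0.252%) and was 40.9% in swi3b. The segment at chromosome 5, 7777301 to 7777900, over AT5G23115, fell in CG from 91.3% to 0.134%. The segment at chromosome 4, 5175701 to 5176300, between AT4G08190 and the pseudogene AT4G08200, fell in CG from 91.3% to 11.9%. CHG fell from 77.6% to 11.6% over the pseudogene AT1G36975, from 73.3% to 14.3% over AT5G36228 and from 59.8% to 4.98% over AT1G34440. Of the 5 segments with the largest CHH losses, 4 lay over pseudogenes. CHH fell from 21.7% to 2.37% over AT5G07215, from 29.2% to 11.1% over AT2G16690, from 21.1% to 6.36% over AT2G16670 and from 15.8% to 1.71% over AT2G07070. Flank CHG fell from 56.3% to 0.183% at AT2G21090, from 55.1% to 0.191% at AT2G21105, from 59.0% to 10.6% at AT1G36980 and from 51.4% to 3.51% at AT2G19380. AT2G21105 lies at the chromosome 2 segment above, and AT2G21090 is the gene before that segment. AT1G36980 is the gene after the segment over AT1G36975. The flank losses at AT2G21090, AT2G21105 and AT1G36980 may therefore repeat losses already given. Body CG fell from 91.7% to 0.521% at AT2G46765 and from 76.8% to 4.17% at AGL92 (AT1G31640), a MADS-box gene. On the forward strand alone the AT2G21105 flanks differed by -19.4 points, short of the threshold.

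Over 100 bp windows, 8841 of 303917 had less CHG methylation in sil1 and 61 had more. Of the lower windows, 57.3% were pericentromeric and 37.3% lay in pseudogene bodies. These shares were above those of all windows tested, 21.8% and 15.06%, but below those of the 87327 windows with enough CHG methylation in wild type to fall by the threshold, 63.8% and 49.1%. In the CG context, 2035 of 293138 windows were lower and 562 higher, and in CHH 3500 of 959404 were lower and 763 higher. The windows passed a two-sided Fisher's exact test at a Benjamini-Hochberg adjusted p under 0.01 and differed by at least 40 points in CG, 20 in CHG or 10 in CHH. Over the alternatives the lower windows numbered 727 to 2035 in CG, 1334 to 9827 in CHG and 188 to 3500 in CHH, the smallest counts coming from leaving out highly covered cytosines, from the stricter differences and from scaling the reads down for the variance between the strands, in that order.

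The swi3b library lost methylation at few loci, and most of the segments lower in CG or CHG were lower in sil1 as well. Of the CHG-methylated segments, 76 of 16473 were lower and 45 higher in CHG, 29 of 13878 were lower and 0 higher in CG, and 198 of 28702 were lower and 55 higher in CHH. The median CHG difference was 1.99 points (95% interval 1.89 to 2.11). In CHG, 4 of 4297 pseudogene bodies were lower and 4 were higher, and the median difference over these bodies was 2.19 points. Among protein-coding genes, 8 of 25302 bodies were lower in CG, and 10 of 25246 bodies and 10 of 27252 flanks were lower in CHG. With segments chosen by the mean of the libraries, 26 were lower and 53 higher in CHG and 4 were lower in CG. That choice tends to leave out windows that lost most of their CHG methylation in both mutants. Part of the fall in these counts was therefore fixed beforehand. The CG segments lower in swi3b numbered 7 when highly covered cytosines were left out, and the stricter differences left 18 segments lower in CHG and 14 in CHH.

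The protein-coding bodies with the largest CG losses in swi3b were those of AT3G29633, AT3G44006 and QQS (AT3G30720), a starch-related gene of Arabidopsis known for naturally varying methylation. The AT3G29633 body had a CG level of 89.7% in wild type, 0.430% in swi3b (95% interval 0.146 to 1.26) and 28.4% in sil1. The AT3G44006 body had 82.6%, 0% (0 of 391 reads, upper limit 0.973%) and 0.518%. The QQS body had 62.9%, 0.239% and 1.53%, and its CHG level was 37.2%, 0.401% and 0.832%. In the intergenic segment at chromosome 3, 10713701 to 10714300, between AT3G05535 and AT3G28580, CG methylation was 77.0% in wild type (435 reads), 1.43% in swi3b (420 reads) and 29.9% in sil1, and CHG methylation was 35.6%, 0.152% and 0.487%. The segment at chromosome 2, 184001 to 184700, over the noncoding RNA gene AT2G01422 and between the auxin efflux carrier gene PIN4 and the homeobox gene HB17, had CG levels of 85.5%, 33.3% and 0% (0 of 798 reads, upper limit 0.479%) and CHG levels of 53.8%, 14.3% and 0.249%. At chromosome 5, 7777301 to 7777900, over AT5G23115, the CG level was 91.3%, 44.8% and 0.134%. Beside VIM3 (AT5G39550), of the family that recruits the CG methyltransferase, the segment at chromosome 5, 15841001 to 15841500, had CG levels of 64.1%, 18.4% and 12.8%. The segment at chromosome 1, 12401401 to 12401900, near SAMC2 (AT1G34065), had CG levels of 86.0%, 41.4% and 58.8%, and was lower in swi3b but did not pass the threshold in sil1.

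**Figure D3:**
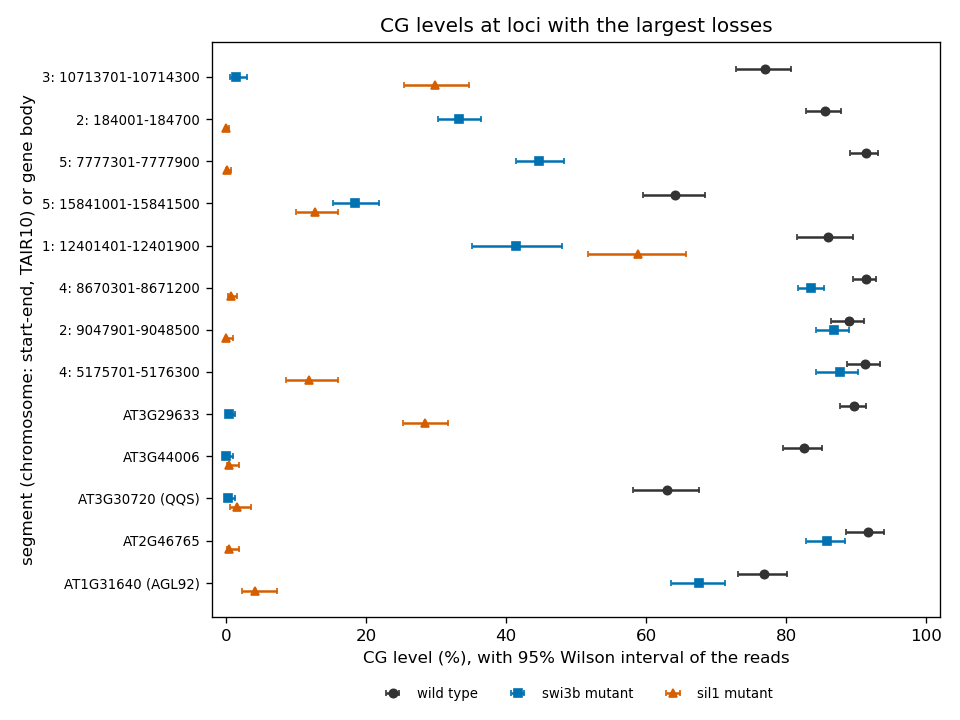
CG methylation level (%, x axis) with its 95% Wilson interval at the segments and gene bodies with the largest CG losses in either mutant (y axis), 1 point per library. Wild-type points lie between 62.9% and 91.7%, while the swi3b point of QQS lies at 0.239% and the sil1 point of chromosome 2, 184001 to 184700 at 0%.

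CHG fell in swi3b at further loci. It fell from 55.3% to 21.2% at chromosome 2, 2325701 to 2326400, over the noncoding RNA gene AT2G05995 beside MOD1, from 44.9% to 11.97% at chromosome 2, 1944701 to 1945200, over AT2G04895, and from 51.1% to 24.6% at chromosome 1, 20032601 to 20033100, over AT1G53655, and the sil1 levels were 13.5%, 1.64% and 0.997%. In flanks of protein-coding genes, CHG fell from 34.5% to 2.80% at IMPA-4 (AT1G09270), a nuclear import receptor, while sil1 had 25.8%. It fell from 36.9% to 9.99% at HDA17 (AT3G44490), from 36.2% to 9.95% at AT4G11790, from 35.0% to 9.30% at NAC089 (AT5G22290) and from 35.9% to 12.7% at AT5G02870. The cytosines of the reverse strand alone gave -8.04 points at HDA17, -14.9 at NAC089 and -9.85 at AT5G02870, none of which passed. CHH fell from 15.2% to 4.73% over the pseudogene AT4G03650. The 3 segments named for gains in swi3b lay over pseudogenes. CHG rose from 41.7% to 65.2% over AT2G01029, at chromosome 2, 36801 to 37700, though with 19.8 points on the reverse strand alone it did not pass, and from 43.8% to 66.9% over AT2G12670, and CHH rose from 13.5% to 25.6% over AT3G33142. In sil1 none of these 3 passed the threshold.

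Window counts in swi3b were 1261 lower and 546 higher in CG, 396 lower and 266 higher in CHG, and 1187 lower and 546 higher in CHH. Of the windows lower in CHG, 40.9% lay within 1 kb of a protein-coding gene. This was above the 17.4% of all windows tested and the 11.3% of those that could fall by the threshold. Of the windows higher in CHG, 62.8% were pericentromeric, against 21.8% of all windows tested and 21.5% of those that could rise. However, 72.9% of the windows higher in CHG lay in CHG-methylated segments. Of the windows with enough CHG methylation to fall by the threshold, 63.8% were pericentromeric, so the gains showed no excess over methylated windows. Pseudogene bodies held 44.0% of the windows higher in CHG, against 15.06% of all windows tested and 49.1% of those that could fall. They held 2.38% of the windows higher in CG, against 12.4% of all windows tested and 1.16% of those that could rise by the threshold. Over the alternatives the lower windows numbered 390 to 1261 in CG, 67 to 409 in CHG and 29 to 1187 in CHH. The higher windows numbered 153 to 549, 29 to 280 and 3 to 546.

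The 45S rRNA genes stood apart in swi3b. Over the 4 nuclear rRNA genes of the table, the CG level was 78.4% in wild type (95% interval 78.1 to 78.7), 53.0% in swi3b (52.4 to 53.5) and 74.5% in sil1 (74.2 to 74.9). The CHG level was 51.5%, 34.2% and 41.8%, and the CHH level 9.56%, 7.32% and 10.2%. These genes took 0.101% of the nuclear CG reads in wild type, 0.0404% in swi3b and 0.0982% in sil1. Relative to all nuclear CG reads of each library, swi3b had 0.271 times the methylated CG reads and 0.867 times the unmethylated CG reads of wild type at these genes. By 100 kb window, its read share was lower than wild type by a log2 ratio of -0.66 at the first 100000 bp of chromosome 2 and of -0.46 at 14200001 to 14300000 of chromosome 3, against an SD of 0.04 over 1193 windows. In sil1 the lowest ratio was that of the same chromosome 3 window, -0.22, against an SD of 0.08, whereas in swi3b the chromosome 2 window was lowest. AT2G01020 passed the threshold in CHG, which fell from 50.8% to 29.0%. The CG differences of the 4 genes, between -12.4 and -31.8 points, were under the threshold of 40. The rRNA genes are present in many copies that share reads, so the values are averages over copies.

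**Figure D4:**
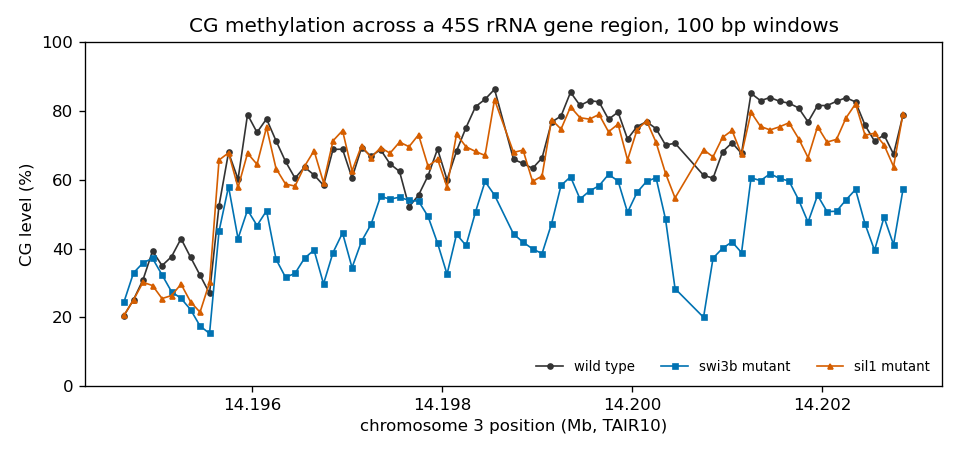
CG methylation level (%, y axis) in 100 bp windows across a 45S rRNA gene region of chromosome 3, 14194601 to 14202900 (Mb, x axis), 1 line per library. The swi3b line is below wild type in 76 of 80 windows, while the sil1 line is below it in 53 of 80.

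Windows lower in swi3b were often lower in sil1. In CG, 636 windows were lower in both mutants, 50.4% of those lower in swi3b, where independent lists would share 8.75. In CHG the number was 296, or 74.7% of those lower in swi3b, against 11.5, and in CHH 453, or 38.2%, against 4.33. Unchanged libraries simulated against the same wild-type library had 0 calls each, so that they give no measure of sharing between calls. The correlation of the differences from wild type across windows, which are not independent replicates, did not exceed that of these unchanged libraries. It was 0.511 in CG against 0.514 in the simulation, 0.237 in CHG against 0.511, and 0.474 in CHH against 0.512. The covariance of the differences in CG was 31.8 squared points against 6.33 in the simulation, in CHG 10.96 against 8.26, and in CHH 2.45 against 1.07. The simulated reads carried binomial variance only, whereas the variance between strands averaged 1.92, 2.21 and 4.02 times binomial in CG, CHG and CHH. The simulated covariances may therefore be too small, and the higher observed values in CHG and CHH do not by themselves show shared change. Windows higher in both mutants numbered 169 in CG, 11 in CHG and 50 in CHH, where independent lists would share 1.05, 0.0534 and 0.434. Where each mutant was compared with its own random part of the wild-type reads, 532 CG, 199 CHG and 204 CHH windows were lower in both. With swi3b compared on the forward strand and sil1 on the reverse strand, so that no wild-type read entered both comparisons, 314 CG, 69 CHG and 96 CHH windows were lower in both, where independent lists would share 4.83, 3.30 and 6.50 of all windows, and 10.1, 8.84 and 28.7 of those with enough methylation to fall. The stricter differences left 180 windows lower in both in CG and 80 in CHG, scaling for the variance between the strands left 22 in CHH, and part of the excess may come from the shared wild-type library. Of the segments lower in swi3b, 19 of 29 in CG, 63 of 76 in CHG and 91 of 198 in CHH were lower in sil1 too.

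Compared directly, the mutant libraries differed most in CHG. Fisher's exact test found 12630 windows with more CHG methylation in swi3b than in sil1 and 79 with less. Of 16473 segments, 2913 had more CHG methylation in swi3b and 4 had less, and the median difference was 11.5 points. In CG, 1379 windows were higher in swi3b and 760 lower, and in CHH 2743 were higher and 1058 lower.

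Few genes of the lists fixed beforehand passed the threshold. None of the 21 genes of DNA methylation and demethylation passed in body or flanks in either mutant, adjusted over all genes or over the list alone. ROS1, a demethylase gene, had a CG level in its flanks of 10.3% in wild type, 10.3% in swi3b and 11.4% in sil1. The CHH level of the ROS1 flanks was 2.72%, 1.03% and 1.62%. The body of IBM1, a histone demethylase gene, had CHG levels of 6.40%, 5.35% and 3.03%. These ROS1 and IBM1 features started too low to be called lower. None of the 13 SWI/SNF genes passed. Over all protein-coding genes, at most 0.978% of bodies or flanks were lower in any context in either mutant. Lists of this size would thus rarely hold a call, and their counts say little about these genes. Of 8 histone deacetylase genes, HDA9 (AT3G44680) was lower in the CHG level of its flanks in both mutants, from 27.2% to 7.11% in swi3b and 5.84% in sil1, also adjusted over the list alone. On the forward strand alone these differences were -2.52 and -10.9 points and did not pass. Of 15 genes with known epialleles or methylation-dependent silencing, QQS was lower in both mutants, in CG and CHG over its body. FWA, a homeobox gene silenced by methylation, had body CG levels of 52.5%, 58.6% and 42.3%, and the flanks of SDC, an F-box gene, had CHG levels of 55.4%, 58.5% and 45.3%, with no call at either gene. Of the 13 transposable element genes, AT5G17125, of a Copia retrotransposon, was lower in flank CHG in sil1, from 38.5% to 9.40%, and had 28.8% in swi3b. The median flank CHG difference of that list was -8.47 points in sil1 and 2.06 in swi3b, at percentiles 15.4 and 77.4 of 10000 random lists of pseudogenes matched on level. Of the 60 list medians without the rRNA genes, 3 lay below percentile 5 or above percentile 95, where chance gives 6. They were the flank CHG of the DNA methylation genes in swi3b, 0.177 points at percentile 99.3, the body CHG of the SWI/SNF genes in swi3b, -0.120 points at percentile 3.85, and the body CG of the genes with known epialleles or silencing in sil1, -0.869 points at percentile 3.05. The rRNA genes had a median body CG difference of -24.1 points in swi3b, at percentile 0 of the random lists, and -3.13 in sil1, at percentile 30.3. Because their copies share reads, the rRNA genes are not independent members, unlike the genes of the random lists. Their percentiles are descriptive only. Of the 12 medians of the rRNA genes, which repeat the same genes over contexts, bodies and flanks, 8 lay outside percentiles 5 and 95. Those of swi3b were all lower, while CHH in sil1 was higher by 0.397 points in bodies, at percentile 96.9, and by 0.620 points in flanks, at percentile 99.5.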

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

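The tests of bisulfite conversion in both mutants and of single strands for the shared windows were chosen after the result was seen, and the others before. The nuclear CHG level moved in opposite directions in the mutants, by 0.6998 percentage points in swi3b and by -4.3416 in sil1 relative to wild type. This difference between the genotypes was not tested, because each has 1 library.

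The CHG loss of sil1 was weighed against 3 technical explanations. Fewer reads from heterochromatin would change the genome-wide level but not the segments, yet the median over segments, each counted once, was -9.68061 points. More complete conversion in sil1 needs unconverted cytosines in wild type, which would show in its chloroplast as well, but the chloroplast CHG level of wild type was 0.124644%. Choosing segments by their wild-type level would bias the difference downwards, but segments chosen by the swi3b library gave a median of -9.45326 points. A candidate explanation that stays open is that the sil1 mutation, in a histone deacetylase gene, lowers CHG methylation of heterochromatin, which is a hypothesis from 1 library per genotype.

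The lower CG methylation and read share at the 45S rRNA genes in swi3b were weighed in the same way. The chloroplast CG level of wild type, 0.134798%, argues against unconverted cytosines in wild type as the source of a difference of -25.4 points. Loss of fully methylated gene copies alone would leave the unmethylated reads, relative to all nuclear CG reads, at about the wild-type value. Lost copies with some unmethylated CG sites would lower this value as well. The unmethylated reads were 0.867327 times the wild-type value, between the bounds set for and against, and the methylated reads 0.270541 times. How methylated any lost copies were was not measured. A loss of copies alone thus cannot be told apart from a loss with some change of methylation in those left. A difference in rRNA gene copy number between the plants, by genotype or by line, may underlie the lower read share.

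The windows lower in both mutants exceeded independent lists, as did those higher in both. If counting error of the shared wild-type library were the cause, the sharing would drop to that of independent lists when swi3b was compared on the forward strand and sil1 on the reverse strand. Within classes of wild-type level and coverage, the number lower in both was then still 10.6736 times that of independent lists in CG (95% interval 9.57 to 11.9), 5.81057 times in CHG (4.77 to 6.86) and 1.9137 times in CHH (1.55 to 2.27), which argues against this error as the whole cause in each context and leaves open that it adds a part. Methylation that only the wild-type plants gained or lost would give shared gains as well as shared losses. The ratio of CG windows higher in both to those lower in both was 0.265723, between the bounds. In CG, this explanation thus cannot be told apart from shared losses in the mutants with 1 wild-type library. In CHG 11 windows were higher in both and 296 lower, and in CHH 50 and 453, but bounds were set for CG alone. QQS, among the shared losses, is known for methylation that varies between wild-type plants.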

How the results depend on the processing

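Every alternative kept more lower than higher windows in each mutant and context. Among segments in swi3b, however, 38 were lower and 45 higher in CHG with highly covered cytosines left out, and 26 were lower and 53 higher with segments chosen by the mean of the libraries. Thinning to equal depth changed no count by over 1.5 times. The signs of the nuclear level differences and of the segment medians held under every alternative, except that the CG difference of swi3b was 0.0951 points without the 45S rRNA regions and its CHG difference -0.426 points with highly covered cytosines left out library by library. The first alternative removes regions with fewer methylated reads in swi3b. The second leaves different cytosines in each library, and with the same cytosines in all libraries the value was 0.639 points. The causes of other changes were not tested. Alternatives chosen after seeing the data were the scaling by strand variance, segments chosen by the mean of the libraries, leaving out the 45S rRNA regions, the coverage limit for levels, those with the same cytosines, single strands for the overlap, and those of the segment medians. Counts fall by construction where fewer windows are tested, as with 10 reads, where 151031 CG and 141306 CHG windows remained, and with the coverage limit, where 122274 and 139407 did. Segments chosen by the mean also lose lower segments by construction, since windows that lost CHG methylation in both mutants tend to be left out.

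A minimum of 10 reads gave 634 CG windows lower in swi3b and 1052 CG windows lower in sil1. It left 218 CG windows higher in swi3b and 221 CG windows higher in sil1, with 327 CG and 196 CHG windows lower in both. It gave 16 CG and 34 CHG segments lower in swi3b and 63 CG and 1276 CHG segments lower in sil1. Windows of 200 bp gave 360 CHH windows lower in swi3b and 1374 CHH windows lower in sil1. They gave 206 CHH windows higher in swi3b and 217 CHH windows higher in sil1, with 149 CHH windows lower in both. The stricter differences left 390 CG, 105 CHG and 114 CHH windows lower in swi3b and 735 CG, 1334 CHG and 276 CHH windows lower in sil1. They left 153 CG, 37 CHG and 43 CHH windows higher in swi3b, 148 CG, 11 CHG and 51 CHH windows higher in sil1 and 180 CG, 80 CHG and 42 CHH windows lower in both. They left 8 CG, 18 CHG and 14 CHH segments lower in swi3b and 51 CG, 133 CHG and 35 CHH segments lower in sil1. Leaving out highly covered cytosines left 470 CG, 67 CHG and 666 CHH windows lower in swi3b and 727 CG, 1630 CHG and 1640 CHH windows lower in sil1. It left 278 CG and 40 CHG windows higher in swi3b and 281 CG, 12 CHG and 487 CHH windows higher in sil1. It left 7 CG and 38 CHG segments lower in swi3b and 34 CG and 1354 CHG segments lower in sil1. Scaling for strand variance left 156 CHG and 29 CHH windows lower in swi3b and 1667 CHG and 188 CHH windows lower in sil1. It left 355 CG, 29 CHG and 3 CHH windows higher in swi3b and 9 CHG and 10 CHH windows higher in sil1, with 118 CHG and 22 CHH windows lower in both. Splitting the wild-type reads left 204 CHH windows lower in both, and single strands, with fewer windows and reads, left 314 CG, 69 CHG and 96 CHH windows. Choosing segments by the mean of the libraries gave 4 CG and 26 CHG segments lower in swi3b and 58 CG segments lower in sil1. The median CHG difference over segments was 2.11 points in swi3b and -10.5 in sil1 with highly covered cytosines left out, 2.22 and -9.44 with segments chosen by the mean, and -9.44 in sil1 with 10 reads.

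The nuclear level differences from wild type, in percentage points, were, with 10 reads, -0.335 in CG, 0.867 in CHG and -0.0356 in CHH for swi3b and -3.78 in CG, -4.67 in CHG and -0.659 in CHH for sil1. With equal weights for cytosines they were -0.674 in CG, 0.282 in CHG and -0.0932 in CHH for swi3b and -1.66 in CG, -3.47 in CHG and -0.518 in CHH for sil1. After removal of the chloroplast level they moved to -0.0447 in CHH for swi3b and -0.598 in CHH for sil1. The forward strand gave -0.623 in CG, 0.644 in CHG and -0.0529 in CHH for swi3b and -3.33 in CG and -0.608 in CHH for sil1. The reverse strand gave -0.198 in CG, 0.756 in CHG and -0.0470 in CHH for swi3b and -3.24 in CG and -0.624 in CHH for sil1. Without the 45S rRNA regions they were 0.0951 in CG, 0.885 in CHG and -0.0376 in CHH for swi3b and -3.21 in CG, -4.28 in CHG and -0.625 in CHH for sil1. Without highly covered cytosines of each library they were -1.64 in CG, -0.426 in CHG and -0.204 in CHH for swi3b and -0.867 in CG, -3.23 in CHG and -0.481 in CHH for sil1. The same cytosines in all libraries gave -0.351 in CG, 0.790 in CHG and -0.0425 in CHH for swi3b and -2.74 in CG, -4.08 in CHG and -0.566 in CHH for sil1. Equal weights over the same cytosines gave -0.524 in CG, 0.520 in CHG and -0.0699 in CHH for swi3b and -0.398 in CG, -2.85 in CHG and -0.395 in CHH for sil1. The coverage limit over the same cytosines gave -0.360 in CG, 0.639 in CHG and -0.0159 in CHH for swi3b and -2.47 in CG, -3.79 in CHG and -0.641 in CHH for sil1.

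Of 400 values of named loci under 10 reads or single strands, 390 stayed on their side of the threshold, 9 no longer passed, 1 newly passed and 0 calls reversed. The value that newly passed was the CHG level over AT2G12670 in sil1, with -22.2 points on the reverse strand. Depth limits the calls, since in a simulation of swi3b against wild type 53.0% of 200 windows lowered by 30 points in CHG and 44.0% of 200 lowered by 15 points in CHH were recovered at the coverage of the libraries, and 89.0% and 76.5% at 2 times that coverage, and more than 1 library per genotype would be needed for any test between genotypes.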

Other observations

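The few CG gains lay mostly in gene bodies, where losses were still more frequent. Of 546 CG windows higher in swi3b and 562 higher in sil1, 66.8% and 67.3% lay in bodies of protein-coding genes, against 39.7% of all windows tested and 52.4% of those that could rise by the threshold. These were 365 and 378 windows, fewer than the 547 and 793 body windows lower in CG. The read-weighted CG level over protein-coding bodies was 17.7% in wild type and 16.9% in both mutants, and 0 bodies were higher by Fisher's exact test. The median CG difference over bodies was however 0 points in both mutants. A negative difference was seen in 47.4% of bodies in swi3b and 45.3% in sil1. Windows called higher in CHH lay mostly in pericentromeres. Of the 546 CHH windows higher in swi3b, 67.2% were pericentromeric, as were 61.9% of the 763 higher in sil1, against 18.6% of all CHH windows tested. Of the windows with enough CHH methylation in wild type to fall by the threshold, 61.9% were pericentromeric. The shares of the gains were thus close to that of methylated windows. Few of these CHH gains stayed after scaling for the variance between strands, as given above. Their shares may therefore describe noise calls rather than true gains. Of the windows lower in CHH, 30.2% in swi3b and 37.1% in sil1 were pericentromeric.

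Of the 296 CHG windows lower in both mutants, 40.9% were within 1 kb of a protein-coding gene and 28.7% were pericentromeric. For the 100 windows lower in swi3b and not in sil1 these numbers were 41 and 23. For the 8545 windows lower in sil1 and not in swi3b the shares were 15.0% and 58.3%, and the differences were not tested. Windows higher in CHG in swi3b and lower in sil1 numbered 9.

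Pericentromeres took 25.3% of the nuclear CG reads in wild type, 25.3% in swi3b and 23.5% in sil1. On chromosome 2, 3400001 to 3500000, the read share was above wild type by a log2 ratio of 0.16 in swi3b and 0.34 in sil1. The cause was not tested, so that this share alone does not show a change of nuclear copies.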
